A study of Homo sapiens with 9 samples.

How the data were processed

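RNA-seq libraries from BxPC3, an established human pancreatic ductal adenocarcinoma cell line, were analysed in 3 groups of 3 libraries that the labels call biological replicates. The groups were vehicle-treated cells, cells transfected with small interfering RNA (siRNA) against STAT3, and cells treated with 0.1 µM WB436B, a compound known here only by its code name. Whether the replicates were separate cultures is not said beyond that term, so the p-values measure the spread between these libraries. Total RNA was isolated with an RNeasy kit from Qiagen, and libraries followed standard Illumina procedures, per the labels' protocols. Strandedness, read length, time under treatment and any non-targeting siRNA control are not given in the sources used here.

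The values analysed were FPKM (fragments normalised for transcript length in kilobases and for the mapped fragments of the library), which the authors deposited as one table with a column per library. The table held 60564 human Ensembl gene identifiers with symbols, 9 columns of FPKM and 3 empty columns. The submitters' processing notes name Bowtie 0.12.2 and the genome build mm8. That build is of the mouse, while the identifiers are human, so the build behind the values is uncertain and no coordinates are printed. The program that computed the FPKM values, the annotation release and any filter are not given in the sources used here. FPKM values are not counts, so no count model was applied. FPKM divides by each library's own total, so a change in a few abundant genes or in many weak ones shifts all the others, and fragments shared by overlapping gene models are divided by a rule that is not known here.

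Gene types, exon overlap, transcript length and GC content came from GENCODE release 29, which held 96.5% of the identifiers. Symbols were those of the deposited table. A set of 27 symbols that had been turned into calendar dates was restored from the identifiers, and 2796 identifiers had no symbol. Depth was estimated from the steps between low FPKM values of genes with a single annotated transcript, where a step is the worth of 1 fragment. The estimates were 47200000, 15600000 and 14900000 fragments for vehicle, 19100000, 17000000 and 18400000 for STAT3 siRNA, and 20400000, 18500000 and 16400000 for WB436B. A gene at 1 FPKM therefore rested on about 14.9 to 47.2 fragments per kilobase.

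Genes with at least 1 FPKM in at least 3 of the 9 libraries were tested, which kept 12747 identifiers (21.0%). Values were analysed as log2(FPKM + 1), so fold changes are on that scale and understate the change of weakly expressed genes. All 9 libraries entered one model with a mean per group and no block, fitted with limma 3.58.1 in R 4.3.3 (limma-trend, empirical Bayes with a mean-variance trend, 6 residual degrees of freedom). The contrasts were STAT3 siRNA against vehicle, WB436B against vehicle, and WB436B against STAT3 siRNA, which is also the test of the difference between both treatment effects. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p below 0.05. The ± values given with FPKM are standard deviations over 3 libraries, and SE denotes the standard error of a log2 fold change. Adjusted p-values of genes are from this limma fit.

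A total of 36 gene lists was fixed before the data were examined, as were the tests and the alternatives named as fixed. Lists with at least 5 tested members were tested with camera (preset inter-gene correlation 0.01), which compares a list with all other genes, and adjusted over the lists within a comparison. Camera with an estimated correlation and fry, a self-contained test, were run as alternatives. The count of called members adjusted over the list alone equalled the count adjusted over all genes in 79 of 108 pairs of list and comparison, differed by 1 member in 24, and differed by up to 5 in the other 5 pairs.

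The rule for naming genes was fixed at the same time. It took, in each comparison against vehicle, the 12 genes with the largest change in each direction, and 8 per direction in the comparison of both treatments. These had to be called, to average at least 1 FPKM in the higher group and to have all 3 libraries of one group above all 3 of the other. Pseudogenes, antisense, readthrough, clone-named and unnamed transcripts and sex-linked marker genes were passed over. STAT3, SOCS3, BCL3, MYC, BCL2L1, MCL1, CCND1, BIRC5 and VEGFA were always named, with up to 4 members of each list by smallest adjusted p. A few genes that the rule takes are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

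Alternatives fixed beforehand were pseudocounts of 0.1 and 0.5, no filter or a filter of 5 FPKM, 3 other scalings between libraries (equal totals, median-of-ratios, quantile), fits of only the groups compared, no variance trend, a robust variance model, a replicate block with and without median-of-ratios scaling, stricter thresholds (adjusted p below 0.01, or a change of at least 1.5-fold) and leaving out each of the 9 libraries in turn. Added after seeing the data were protein-coding genes only, removal of genes that differed 4-fold or more between libraries of one group, removal of the trend on transcript length and GC content, and leaving out mitochondrially encoded genes. For the shared vehicle group, 100 simulations drew all 9 libraries anew, vehicle included, around the vehicle mean of each gene and independently between genes. Both unchanged groups were then compared with the simulated vehicle group. The fit, the list test, the depth estimate and the removal of the length and GC trend were tested on simulated data beforehand. With 200 genes changed among 12747, the fit recovered 73.1%, 70.1% and 73.1% of genes changed by 0.5 on the log2 scale, in the order of the comparisons above. At a change of 1 it recovered 98.5%, 97.0% and 94.0%. False calls, counted over the whole fit with all sizes of change, numbered 7, 9 and 6. The changed genes were drawn from better-expressed genes only, so recovery of the weakest tested genes was not measured. Far fewer genes were changed than were called in the data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.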

Results

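Transcript levels were measured by RNA-seq in BxPC3 cells under vehicle, after transfection of siRNA against STAT3, and under 0.1 µM WB436B, with 3 libraries per group. The libraries of a group were alike, with Pearson correlations of log2(FPKM + 1) across the tested genes of 0.980 to 0.988 within groups and 0.918 to 0.941 between groups. No pair of libraries shared more than 5 identical values, so all 9 were counted as separate. The first principal component held 53.3% of the variance and separated WB436B from the other libraries, and the second held 27.1% and separated STAT3 siRNA from vehicle. Estimated depth lay between 14900000 and 47200000 fragments per library.

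STAT3, the transcription factor targeted by the siRNA, stood at 16.4, 15.8 and 15.1 FPKM in the vehicle libraries and at 2.98, 2.58 and 3.02 FPKM in the STAT3 siRNA libraries. The siRNA group held 18.1% of the vehicle mean, a log2 fold change of -2.12 (SE 0.0573, adjusted p = 1.0e-07). Under WB436B the STAT3 transcript stood at 10.5, 10.9 and 10.8 FPKM, 68.0% of the vehicle mean, with a log2 fold change of -0.52 (adjusted p = 6.5e-05). SOCS3, a feedback inhibitor of JAK-STAT signalling that STAT3 induces, fell from 5.56 ± 0.599 FPKM under vehicle to 0.971 ± 0.157 FPKM after the siRNA. It was 4.10 ± 0.214 FPKM under WB436B, a log2 fold change of -0.36 (adjusted p = 0.0060) whose call was lost under quantile normalization (-0.19, adjusted p = 0.091). The difference of SOCS3 between the treatments was 1.37 on the log2 scale (adjusted p = 3.5e-06). An exact permutation test of STAT3 in 3 against 3 libraries gave p = 0.1 in each comparison against vehicle, the smallest this design allows.

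**Figure D1:**
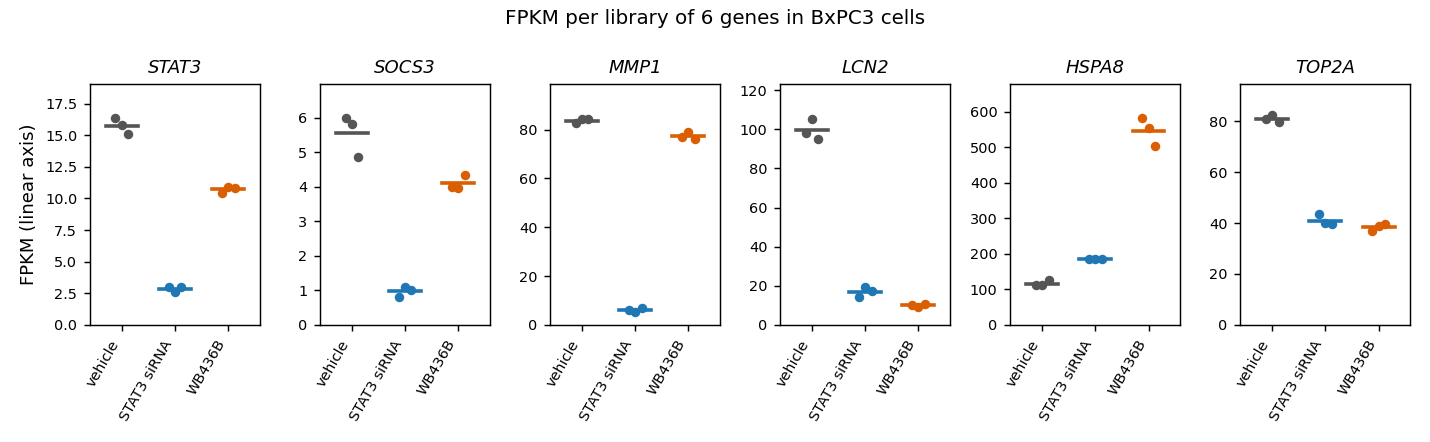
FPKM of 6 genes in each library (points, linear axis) with the group mean (line), for vehicle, STAT3 siRNA and WB436B, 3 libraries each. STAT3 averages 15.8, 2.86 and 10.7 FPKM, MMP1 83.7, 6.09 and 77.3 FPKM, and HSPA8 116, 185 and 546 FPKM in the 3 groups.

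The comparison of STAT3 siRNA with vehicle asks which transcripts change when STAT3 is depleted in these cells. The largest decrease was in MMP1, an interstitial collagenase, which fell from 83.7 ± 1.00 to 6.09 ± 0.625 FPKM (log2 fold change -3.58, SE 0.0613, adjusted p = 1.0e-08). PLAT, the tissue plasminogen activator, fell from 26.0 ± 3.87 to 1.80 ± 0.137 FPKM. DUOX2 and its maturation factor DUOXA2, which make up a hydrogen peroxide-producing oxidase, fell by 3.09 and 3.05 on the log2 scale. SERPINB3 fell from 149 ± 6.94 to 21.1 ± 0.312 FPKM, and its neighbour SERPINB4, which has a closely related sequence, fell by 2.67 on the log2 scale. The connexin gene GJB2 fell by 2.70, and PDZK1IP1, FYB1 and TCN1 by 2.75, 2.74 and 2.62. SLURP2 averaged 5.05 FPKM under vehicle and was listed at 0 in all 3 siRNA libraries, but 85.0% of its exon bases are shared with the readthrough gene LYNX1-SLURP2.

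The largest increase after the siRNA was in IGFBP5, a secreted binding protein of insulin-like growth factors, from 0.878 ± 0.0230 to 138 ± 8.30 FPKM (log2 fold change 6.20, SE 0.0534, adjusted p = 1.5e-10). CGA, the common alpha subunit of glycoprotein hormones, rose from 0.896 ± 0.0560 to 18.4 ± 0.428 FPKM. The imprinted non-coding transcript H19 rose from 75.3 ± 31.5 to 624 ± 184 FPKM (log2 fold change 3.09, adjusted p = 0.00014). The trypsinogen genes PRSS1 and PRSS2, near-identical copies whose fragments can be exchanged, rose by 2.75 and 2.49 on the log2 scale. MXD1, a MAX-binding antagonist of MYC, rose by 2.49, DMBT1 by 2.26, the kinase-anchoring protein AKAP12 by 1.94, FAM155B by 1.93 and OSBP2 by 1.88. The small nucleolar RNAs SNORD14D and SNORD14E were also among the 12 largest increases (2.80 and 1.91), although all exon bases of SNORD14D lie within exons of HSPA8.

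In all, 3800 genes were higher and 2838 lower after STAT3 siRNA among 12747 tested, of which 132 and 352 changed at least 2-fold. Of these calls 57.2% were upward, against 48.6% with median-of-ratios scaling (3092 higher and 3275 lower), 54.3% with quantile normalization and 63.5% with equal totals. In 60.5% of tested genes the 3 libraries of one group all lay above those of the other, against 10% by chance. The labels name no non-targeting siRNA, so effects of transfection itself are not separated from those of STAT3 loss in this comparison.

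Among the fixed gene lists, 24 of 33 tested were called after STAT3 siRNA, 5 upward and 19 downward, and 12 of these also passed with an estimated correlation. Of 32 tested textbook targets of STAT3, 22 fell and 3 rose (median log2 fold change -0.81, camera adjusted p = 8.0e-08), with MMP1, TGM2 (-1.71), ICAM1 (-1.57) and LIF (-1.89) at the lowest p. NF-kB targets and inflammatory cytokines fell in 19 of 24 members (median -1.03, adjusted p = 7.2e-09), among them IL1A (-1.44) and the inhibitor gene NFKBIA (-1.28). Acute-phase and complement genes fell in 9 of 10 (median -1.69, adjusted p = 1.5e-06), including C3 (-1.75), ceruloplasmin CP (-2.48), CFB (-2.17) and the siderophore-binding protein LCN2 (-2.50). Ductal and mucin genes fell in 13 of 17 (median -0.50, adjusted p = 1.5e-06), with MUC1 at -1.80 and SPP1 at -2.06. Squamous and basal keratinocyte genes fell in 17 of 26 (median -0.40, adjusted p = 3.0e-06), while KRT17 of that list rose by 1.37. Hypoxia-induced genes fell in 12 of 18 (median -0.50, adjusted p = 9.8e-05), including NDRG1 (-1.68) and DDIT4 (-1.39). ERK feedback and target genes fell in 13 of 23 (median -0.42, adjusted p = 0.00053), with HBEGF at -1.86 and EGR1 at -1.97, while CCND1 (cyclin D1) rose by 0.84.

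Genes of the cell cycle moved in opposite directions after the siRNA. Of 35 G2/M and mitosis genes, 29 fell and 1 rose (median -0.49, camera adjusted p = 4.1e-10), among them KIF20A (-1.26), TOP2A (-0.97) and TPX2 (-0.71). Of 37 DNA replication and G1/S genes, 32 rose and 1 fell (median 0.51, adjusted p = 1.3e-09), with E2F1 at 0.93, GINS2 at 0.89 and CDT1 at 0.78. Ribosome biogenesis genes rose in 25 of 28 (median 0.45, adjusted p = 8.8e-08), and RRP9 rose by 1.25. Cholesterol biosynthesis genes fell in 18 of 24 (median -0.54, adjusted p = 1.5e-06), including SQLE (-1.16). ATF4 and integrated stress response genes rose in 16 of 23 (median 0.39, adjusted p = 0.0035), with TRIB3 at 1.22 and SLC7A5 at 0.79, although DDIT4 of that list fell by 1.39.

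The other called lists lost the call with an estimated correlation, whose adjusted p is given second. Matrix metalloproteinase and plasminogen genes fell in 13 of 20 (median -0.49, adjusted p = 4.2e-05, then 0.066), and ER chaperones such as HSPA5 (-0.84) and HSP90B1 (-0.89) fell in 14 of 22 (median -0.40, adjusted p = 3.0e-05, then 0.066). Heat-shock protein genes rose in 12 of 17 (median 0.39, adjusted p = 0.0038, then 0.066), with HSPH1 at 0.79 and BAG3 at -0.67. Cytosolic ribosomal protein genes rose in 24 of 46 (median 0.34, adjusted p = 0.00098, then 0.44). Antigen presentation genes fell in 11 of 23 (median -0.32, adjusted p = 0.0038, then 0.077), and JAK-STAT components in 13 of 27 (median -0.22, adjusted p = 0.0068, then 0.17). The JAK-STAT list includes STAT3, the target of the siRNA, so part of its decrease is the knockdown itself, and 5 of its members rose. Fatty acid synthesis genes fell in 9 of 15 (median -0.26, adjusted p = 0.017, then 0.14), with SCD at -1.68. TGF-beta response and mesenchymal genes fell in 10 of 18 (median -0.33, adjusted p = 0.018, then 0.22). Replication-dependent histone genes fell in 5 of 8 (median -0.70, adjusted p = 0.014, then 0.12), and glycolysis genes in 9 of 19 (median -0.14, adjusted p = 0.024, then 0.27). Mitochondrially encoded genes fell in 7 of 13 (median -0.23, adjusted p = 0.033, then 0.44), and apoptosis regulators in 8 of 28 (median -0.15, adjusted p = 0.039, then 0.20). The mitochondrially encoded call was lost under quantile normalization, without vehicle 3 (-0.17, adjusted p = 0.088) and without siRNA 2 (-0.19, adjusted p = 0.062), and with no filter, which also ended the TGF-beta and histone calls. The apoptosis call was lost with median-of-ratios scaling, without vehicle 3 (-0.12, adjusted p = 0.070) and without siRNA 2 (-0.14, adjusted p = 0.056), and the glycolysis call without siRNA 3 (-0.15, adjusted p = 0.051).

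Not called after the siRNA were type I interferon-stimulated genes (0.062, camera adjusted p = 0.29), p53 targets (-0.021, 0.12), nuclear-encoded respiratory chain genes (0.15, 0.078), NRF2 targets (0.22, 0.16), aryl hydrocarbon receptor targets (0.43, 0.18), YAP/TAZ targets (0.078, 0.44), epithelial junction genes (0.063, 0.55), tubulins (0.10, 0.56) and housekeeping genes (0.097, 0.54), each with its median log2 fold change and adjusted p. The test of the epithelial junction list pointed downward, against the sign of its median. Fry, which tests a list by itself, called all of these lists except the tubulins (fry adjusted p = 0.076). The respiratory chain list was called without vehicle 3 (0.18, adjusted p = 0.048) or WB436B 3 (0.15, adjusted p = 0.048), with equal totals (0.21, adjusted p = 0.037), under quantile normalization (0.17, adjusted p = 0.041) and in a fit of only both groups compared (0.15, adjusted p = 0.037). Within the interferon-stimulated list 16 of 44 members rose and 8 fell, and ISG15 (1.36) and IFI6 (1.19) rose.

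The comparison of WB436B with vehicle asks which transcripts change under the compound. AKAP12 rose from 4.75 ± 0.459 to 78.9 ± 2.71 FPKM (log2 fold change 3.80, SE 0.0619, adjusted p = 6.9e-09), and IGFBP5 from 0.878 ± 0.0230 to 18.5 ± 0.723 FPKM (3.38). The matrix glycoprotein THBS1 rose from 13.1 ± 0.609 to 109 ± 3.67 FPKM (2.96), and SERPINB2, an inhibitor of plasminogen activators, from 37.3 ± 1.64 to 287 ± 13.1 FPKM (2.91). ANKRD1 and CYR61, both known targets of the YAP/TAZ coactivators, rose by 2.56 and 2.19 on the log2 scale. The cytokine gene CSF2 rose by 2.53, the endothelin precursor EDN1 by 2.34, the chaperone gene HSPA8 by 2.22, the AP-1 component FOSL1 by 2.17 and SH2D5 by 2.11. TOMM6 ranked first (3.98), but its 3 WB436B libraries held 82.2, 22.5 and 9.21 FPKM and all its exon bases are shared with an overlapping gene model.

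Decreases under WB436B were led by TNFSF10, the death ligand TRAIL, from 32.3 ± 1.38 to 2.25 ± 0.140 FPKM (log2 fold change -3.36, SE 0.0586, adjusted p = 8.3e-09). ID1, an inhibitor of basic helix-loop-helix factors, fell from 288 ± 1.28 to 28.9 ± 1.53 FPKM, and LCN2 from 99.5 ± 5.25 to 9.97 ± 0.739 FPKM. The growth factor receptor FGFR3 fell by 3.08 on the log2 scale, DUOX2 by 2.93, DUOXA2 by 2.83, the elastase inhibitor PI3 by 2.92 and complement C3 by 2.92. PIGR, the epithelial transporter of immunoglobulins, fell by 2.84, PDZK1IP1 by 2.74, complement C1R by 2.68 and the epithelial transcription factor ELF3 by 2.64.

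Under WB436B 3168 genes were higher and 5234 lower than under vehicle, of which 324 and 1011 changed at least 2-fold. The split depended on scaling and on the filter, since 37.7% of calls were upward on FPKM as deposited, 49.9% with median-of-ratios scaling and 53.03% with quantile normalization. With the filter of 5 FPKM 50.4% were upward (2448 higher and 2412 lower), and with no filter 29.9% (3148 higher and 7394 lower). The median of all tested genes was -0.13 on the log2 scale, and these scalings moved it by 0.13 and 0.16. List tests compare a list with all other genes and are relative to that median.

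Of the 33 tested lists, 9 were called under WB436B, 5 upward and 4 downward, and 4 of them passed with an estimated correlation. All 28 ribosome biogenesis genes rose (median 1.20, camera adjusted p = 7.0e-17), including DKC1 (1.54), NOP16 (1.23), DDX21 (1.62) and WDR43 (1.26). DNA replication and G1/S genes rose in 29 of 37 (median 0.45, adjusted p = 1.6e-08), with MCM7 at 0.90, MCM6 at 1.00, CDT1 at 0.96 and MCM10 at 1.64. YAP/TAZ targets rose in 11 of 21 and fell in 3 (median 0.75, adjusted p = 0.00029), with F3 at 1.30 and DLC1 at 1.25 beside ANKRD1 and CYR61. Ductal and mucin genes fell in 15 of 17 (median -1.08, adjusted p = 0.00029), with AGR2 at -2.53, CEACAM5 at -2.14 and CEACAM6 at -1.08.

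The other 5 lists called under WB436B lost the call with an estimated correlation, whose adjusted p is given second. Acute-phase and complement genes fell in 9 of 10 (median -2.17, adjusted p = 0.00088, then 0.11), and hypoxia-induced genes in 12 of 18 (median -0.54, adjusted p = 0.023, then 0.11), with DDIT4 at -2.50. Heat-shock protein genes rose in 10 of 17 (median 0.75, adjusted p = 0.0032, then 0.11), with HSPH1 at 1.77, DNAJA1 at 1.31 and HSP90AB1 at 1.19. Squamous and basal keratinocyte genes fell in 18 of 26 (median -0.85, adjusted p = 0.038, then 0.16), with S100A9 at -2.44, although SERPINB2 of that list rose. The squamous call was lost with a pseudocount of 0.1 (adjusted p = 0.052) and in a fit of only both groups compared (adjusted p = 0.051), and the hypoxia call with the filter of 5 FPKM (adjusted p = 0.090). Cytosolic ribosomal protein genes rose in 18 of 46 (median 0.16, adjusted p = 0.00088, then 0.52), or in 13 when adjusted over the list alone, and quantile normalization ended that call (0.035, adjusted p = 0.78).

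The textbook targets of STAT3 were not called as a list under WB436B (median -0.31, camera adjusted p = 0.16), with 18 of 32 lower and 5 higher. JUNB (-1.64) and CEBPD (-2.04) fell while CYR61 and CCND1 (1.16) rose. This list was called under quantile normalization (-0.32, adjusted p = 0.0090) and with the filter of 5 FPKM (-0.36, adjusted p = 0.035). Fry, which does not compare a list with other genes, also called it downward (fry adjusted p = 4.6e-06), like most lists that camera left uncalled. NF-kB targets were not called either (median -0.15, adjusted p = 0.49), with 10 of 24 higher and 10 lower, and their test pointed upward against the sign of the median. G2/M genes missed the threshold (median 0.21, adjusted p = 0.053) with 19 of 35 higher and 11 lower. They passed it without vehicle 2 (0.22, adjusted p = 0.049) or siRNA 3 (0.21, adjusted p = 0.045), with equal totals (0.27, adjusted p = 0.039) and with median-of-ratios scaling (0.35, adjusted p = 0.040), while quantile normalization gave 0.15 (adjusted p = 0.76). CDC20 (1.35) and CCNB1 (0.85) rose and TOP2A fell by 1.05. ATF4 genes also missed it (median -0.52, adjusted p = 0.070), with PSAT1, an enzyme of serine synthesis, at -1.94. They were called under quantile normalization (-0.63, adjusted p = 0.00088), with the filter of 5 FPKM (-0.51, adjusted p = 0.031) and among protein-coding genes only (-0.52, adjusted p = 0.048). Housekeeping genes had a median of 0.11 (adjusted p = 0.17), although ACTB rose by 1.26 and SDHA fell by 0.74.

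The other lists were not called under WB436B either, with the median log2 fold change and camera adjusted p of each as follows. Medians above 0 were found for ERK targets (0.22, 0.21), fatty acid synthesis (0.12, 0.25), cholesterol biosynthesis (0.083, 0.13), TGF-beta response (0.071, 0.25) and glycolysis (0.039, 0.25), and the mean of the fatty acid list was -0.01. Medians below 0 were found for p53 targets (-0.56, 0.20), metalloproteinases and the plasminogen system (-0.44, 0.17), JAK-STAT components (-0.36, 0.086), tubulins (-0.36, 0.19), apoptosis regulators (-0.31, 0.45) and antigen presentation (-0.30, 0.16). They were also below 0 for ER chaperones (-0.25, 0.17), mitochondrially encoded genes (-0.20, 0.25), type I interferon-stimulated genes (-0.17, 0.58), epithelial junction genes (-0.17, 0.40), histone genes (-0.15, 0.50), the nuclear-encoded respiratory chain (-0.13, 0.36), aryl hydrocarbon receptor targets (-0.086, 0.81) and NRF2 targets (-0.074, 0.75). Quantile normalization called the JAK-STAT (-0.34, adjusted p = 0.0094), antigen presentation (-0.39, adjusted p = 0.014), ER chaperone (-0.23, adjusted p = 0.0097), respiratory chain (-0.25, adjusted p = 0.00086) and metalloproteinase lists (-0.30, adjusted p = 0.015). The filter of 5 FPKM called the JAK-STAT (-0.47, adjusted p = 0.030) and ER chaperone lists (-0.28, adjusted p = 0.038). Fry called most of the lists in this paragraph, with p53 targets lower at a fry adjusted p of 9.5e-07.

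Of the other genes named in advance, BCL3 fell by 1.31 under WB436B, MCL1 by 0.70 and VEGFA by 1.13, and BIRC5 rose by 0.66 (adjusted p = 0.012). After the siRNA BCL3 fell by 1.32, MCL1 by 0.56 and VEGFA by 0.75. BIRC5 fell by 0.58 after the siRNA (adjusted p = 0.028), a call lost without vehicle 1 (-0.56, adjusted p = 0.070), vehicle 3 (-0.55, adjusted p = 0.073), siRNA 1 (-0.46, adjusted p = 0.092) or siRNA 2 (-0.50, adjusted p = 0.087). MYC ranged from 2.93 to 13.9 FPKM within the vehicle group and from 3.49 to 11.3 FPKM within the siRNA group. It was not called in either comparison against vehicle (log2 fold changes 0.34 and 1.15, adjusted p = 0.61 and 0.082). Under WB436B it was called without vehicle 3 (1.71, adjusted p = 0.0076) or siRNA 3 (1.15, adjusted p = 0.049). BCL2L1 was not called either (0.48 and 0.74, adjusted p = 0.28 and 0.096), but was under WB436B without vehicle 1 (0.23, adjusted p = 0.014), vehicle 2 (0.98, adjusted p = 0.0496) or vehicle 3 (0.99, adjusted p = 0.044).

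**Figure D2:**
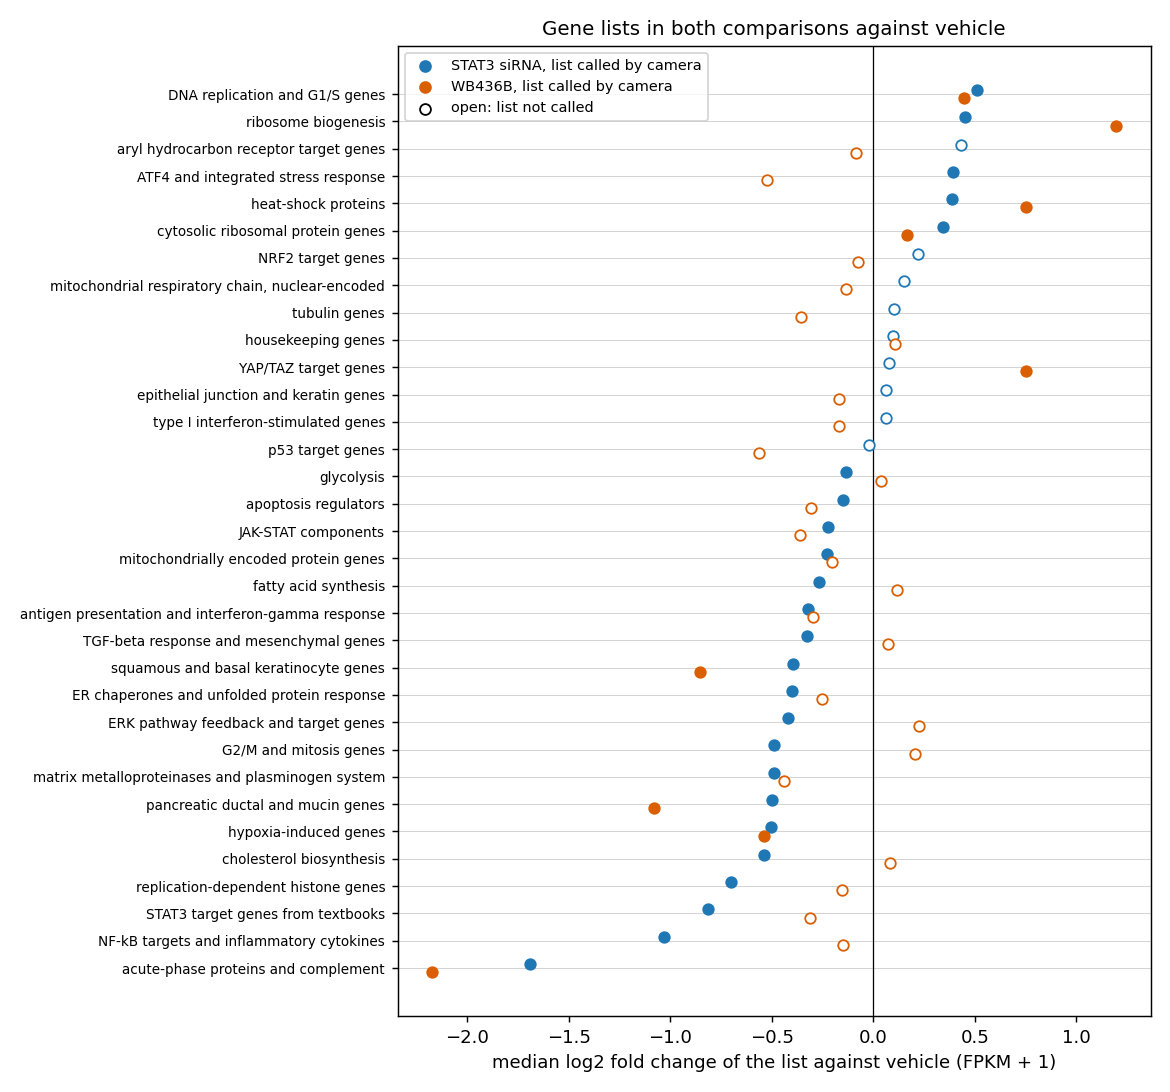
Median log2 fold change against vehicle of each tested gene list (horizontal axis, log2 of FPKM + 1) after STAT3 siRNA and under WB436B. Filled points are lists called by camera at an adjusted p below 0.05, and the acute-phase list lies lowest in both, at -1.69 and -2.17.

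Fewer genes were detected under WB436B. An average of 10870 ± 29.4 genes reached 1 FPKM, against 12236 ± 5.51 under vehicle and 12284 ± 39.5 after the siRNA (exact permutation p = 0.1 against either group, the smallest possible). Long non-coding RNA genes accounted for 365 ± 9.24 of these under WB436B and 798 ± 10.3 under vehicle, protein-coding genes for 9754 ± 22.9 and 10429 ± 23.6. Genes at 100 FPKM or more numbered 296 ± 8.14 under WB436B and 272 ± 10.6 under vehicle. Mitochondrially encoded genes held 37.1% ± 1.94 of the FPKM total under vehicle, 32.4% ± 0.274 after the siRNA and 31.9% ± 0.498 under WB436B.

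**Figure D3:**
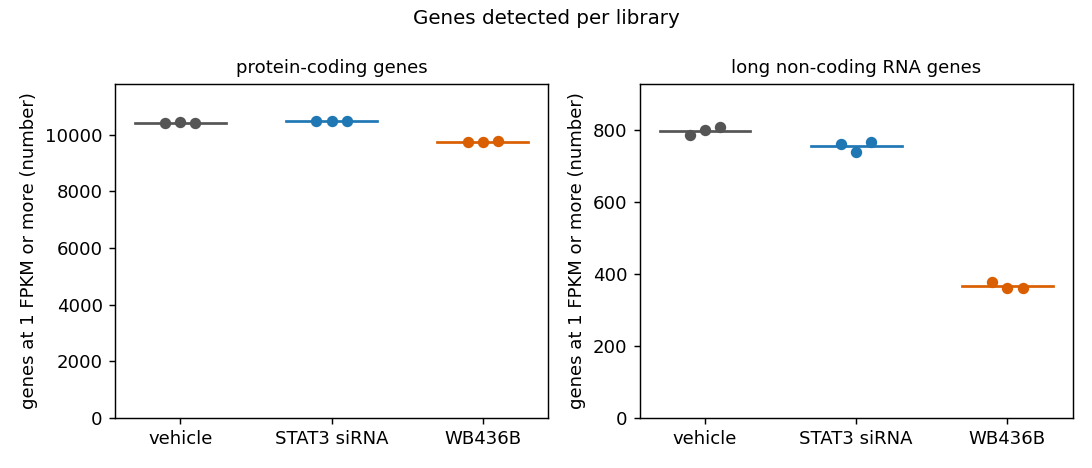
Number of protein-coding genes and of long non-coding RNA genes at 1 FPKM or more in each library (points, axes from 0) with the group mean (line). Long non-coding RNA genes number 787 to 807 under vehicle, 738 to 767 after STAT3 siRNA and 360 to 376 under WB436B.

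The 2 treatments were then set side by side. A set of 2002 genes was lower and 1810 higher in both comparisons with vehicle. Of these, 1316 and 976 were nevertheless called different between the treatments in the direct contrast. The genes lower in both by the largest margin included DUOX2, DUOXA2, PDZK1IP1, LCN2, CP and PIGR, and those higher in both included IGFBP5, AKAP12 and MXD1. The argininosuccinate synthase gene ASS1 fell from 62.8 ± 1.77 FPKM to 11.6 ± 0.790 after the siRNA and 11.4 ± 0.599 under WB436B, and LY6D from 52.6 ± 7.03 to 9.02 ± 0.505 and 9.34 ± 0.617 FPKM. ASS1 and LY6D, like SRM below, were chosen after their values were seen. SRM, spermidine synthase, rose from 9.45 ± 0.829 to 36.7 ± 1.66 and 27.0 ± 0.601 FPKM. Of the shared genes, 198 were at least 2-fold lower and 37 at least 2-fold higher in both. Opposite calls were made for 827 genes (siRNA higher, WB436B lower) and 357 genes (siRNA lower, WB436B higher).

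Both comparisons use the same 3 vehicle libraries, which makes their fold changes correlate without any shared effect. Independent lists of these sizes would share 1165 lower and 944 higher genes, and would hold 1560 and 705 opposite pairs. Unchanged groups compared with one simulated vehicle group shared 0.02 calls on average. The vehicle values were drawn anew and independently between genes, so a deviation of the real vehicle libraries across many genes is not covered. Pearson's r of the fold changes across genes, which are not independent replicates, was 0.531, while the simulated unchanged groups gave 0.505 on average and up to 0.564, above the observed value (Spearman's rho 0.492, against 0.462 and up to 0.483). The fold changes had the same sign in 64.0% of genes, against 66.7% on average in the simulation. For unchanged groups the shared vehicle group alone sets the correlation and the share of equal signs, at any size of the noise. Their simulated values are no baseline for groups with many changed genes. Neither measure can therefore tell a shared response from shared controls. The covariance does depend on the size of the changes. It was 0.155, against 0.0103 on average and up to 0.0124 in the simulation, a difference of 0.145 from that average. Vehicle noise that is independent between genes would supply only a small part of it, while a deviation across many genes is not covered. The 3 vehicle libraries cannot be divided into parts of at least 2 libraries each, so part of the excess of shared calls over independent lists may come from the shared controls.

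**Figure D4:**
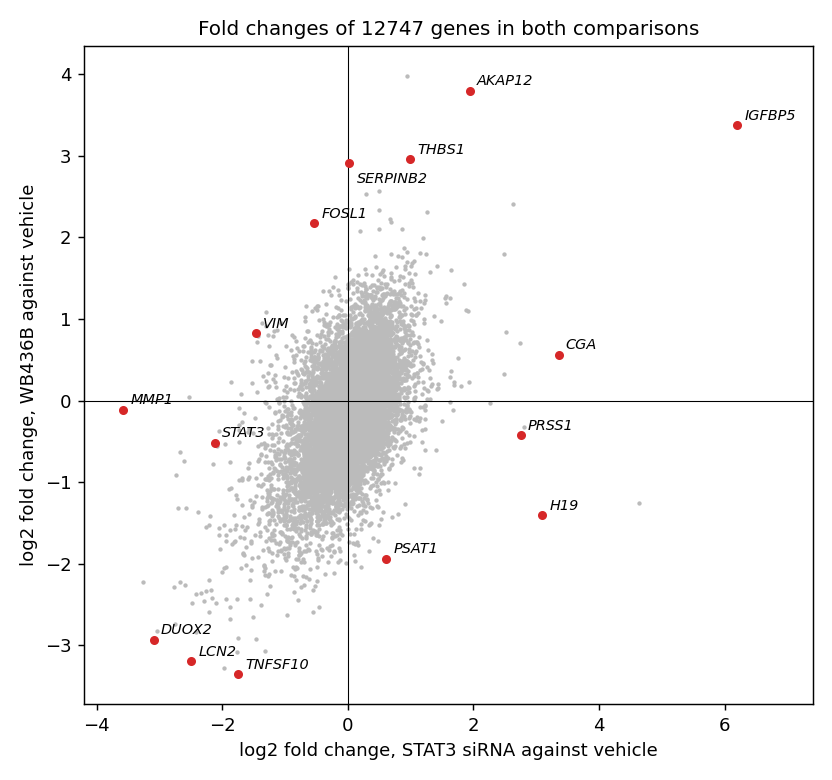
Log2 fold change against vehicle of the 12747 tested genes after STAT3 siRNA (horizontal) and under WB436B (vertical), one grey point per gene, with 15 genes in red. IGFBP5 lies at 6.20 and 3.38, MMP1 at -3.58 and -0.11, and H19 at 3.09 and -1.40.

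The direct contrast of WB436B with STAT3 siRNA called 2554 genes higher and 5621 lower under WB436B, of which 267 and 651 differed at least 2-fold. The share of upward calls was 31.2%, and 50.6% with median-of-ratios scaling and 49.99% with quantile normalization, which moved the median of all genes by 0.18 each. With the filter of 5 FPKM it was 44.2%, and with no filter 25.7%. MMP1 differed most in the upward direction (log2 difference 3.47, adjusted p = 1.5e-08), and stood at 77.3 ± 1.53 FPKM under WB436B, a log2 fold change of -0.11 against vehicle (adjusted p = 0.13). FGFBP1, a secreted carrier of fibroblast growth factors, showed the same pattern with 74.1 ± 1.15 FPKM under vehicle, 12.1 ± 1.77 after the siRNA and 76.6 ± 0.605 under WB436B. SERPINB2 (2.88), FOSL1 (2.71), PHLDA2 (2.39) and the intermediate filament gene VIM (2.29) were also higher under WB436B, although 24.4% of VIM exon bases are shared with its antisense gene. TOMM6 (3.04) and TXNDC5 (2.32, adjusted p = 0.019) were in the same group. TXNDC5 ranged from 5.76 to 44.9 FPKM among the siRNA libraries, and its call was lost without siRNA 1 (1.98, adjusted p = 0.065) or siRNA 3 (1.80, adjusted p = 0.065) and with no filter. Lower under WB436B than after the siRNA were H19 (-4.50), PRSS1 (-3.18), SNORD14D (-3.12), IGFBP5 (-2.83), CGA (-2.79), PSAT1 (-2.55), DMBT1 (-2.28) and the troponin gene TNNI2 (-2.25).

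Of the 33 lists, 14 differed between the treatments, 12 higher and 2 lower under WB436B, and 8 passed with an estimated correlation. NF-kB targets were higher in 21 of 24 members and lower in none (median 0.80, camera adjusted p = 3.9e-11), with IL1A at 2.23 and IL1B at 1.98. Ribosome biogenesis genes were higher in 25 of 28 (median 0.69, adjusted p = 4.3e-14), G2/M genes in 23 of 35 (median 0.63, adjusted p = 1.9e-09) and cholesterol biosynthesis genes in 18 of 24 (median 0.76, adjusted p = 2.3e-09). ERK feedback and target genes were higher in 13 of 23 (median 0.31, adjusted p = 3.3e-05), with HBEGF at 2.08 and AREG at 2.02, and YAP/TAZ targets in 12 of 21 (median 0.35, adjusted p = 1.5e-05). STAT3 targets were higher in 14 and lower in 8 of 32 (median 0.27, adjusted p = 0.00023), a call that was lost with the filter of 5 FPKM (0.25, adjusted p = 0.070). ATF4 genes were lower in 20 of 23 and higher in none (median -0.80, adjusted p = 8.9e-06), with AARS at -1.02, NUPR1 at -1.43 and ATF4 itself at -0.97.

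The remaining 6 of these lists lost the call with an estimated correlation, whose adjusted p is given second. They were glycolysis (median 0.33, adjusted p = 0.00030, then 0.15), TGF-beta and mesenchymal genes (0.32, adjusted p = 0.00057, then 0.13), fatty acid synthesis (0.38, adjusted p = 0.0024, then 0.10), heat-shock proteins (0.70, adjusted p = 0.0063, then 0.10), matrix metalloproteinases and the plasminogen system (0.25, adjusted p = 0.018, then 0.27) and, lower under WB436B, the nuclear-encoded respiratory chain (-0.36, adjusted p = 0.034, then 0.49). The heat-shock and metalloproteinase calls were also lost under quantile normalization and with the filter of 5 FPKM, the latter and the respiratory chain call with median-of-ratios scaling, and the respiratory chain call without WB436B 3 (-0.30, adjusted p = 0.084). Acute-phase genes were not called (median -0.55, adjusted p = 0.20), nor were DNA replication genes (0.037, adjusted p = 0.16), whose mean was -0.05 and whose test pointed upward. Quantile normalization also called type I interferon-stimulated genes (-0.26, adjusted p = 0.017), NRF2 targets (-0.42, adjusted p = 0.0016), tubulins (-0.47, adjusted p = 0.042) and epithelial junction genes (-0.30, adjusted p = 0.030) lower under WB436B, and median-of-ratios scaling ER chaperones higher (0.30, adjusted p = 0.030).

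Markers of cell types other than the cultured line were low. Of 14 fibroblast genes 4 passed the filter, of 16 blood and endothelial genes 2, and of 21 acinar and endocrine genes 3, too few for a list test. Summed FPKM of the fibroblast list was 8.45 ± 0.448 under vehicle, 8.35 ± 0.256 after the siRNA and 8.09 ± 0.470 under WB436B. Blood and endothelial genes summed to 8.69 ± 1.55, 5.89 ± 1.30 and 4.51 ± 0.132 FPKM, with CD68 the most abundant. CD68 was not called after the siRNA (log2 fold change -0.45, adjusted p = 0.060) except without siRNA 2 (-0.67, adjusted p = 0.0026) and in fits with median-of-ratios or quantile scaling. Acinar and endocrine genes summed to 19.4 ± 1.36, 28.1 ± 0.692 and 17.2 ± 1.90 FPKM, with PRSS1 the largest member after the siRNA.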

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

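The tests of depth, of the most abundant genes, of scaling for the opposite lists, of fragment number, of length and GC content, of protein-coding genes only and without mitochondrially encoded genes were chosen after the result was seen, while those of background, single libraries, shared exons and transcripts per gene were set down before.

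The direct contrast and both comparisons with vehicle were searched for results that differed between the treatments in direction. A gene had to be called in opposite directions against vehicle and to be called in the direct contrast, which 7 of 57 genes considered met. With the same demand for lists, opposite calls and a called direct difference, camera found 0 of 33 on FPKM as deposited. It found 2 at an unadjusted p under 0.05 and 0 with an estimated correlation, and fry found 11. The G2/M list met it with equal totals (WB436B adjusted p = 0.039), with median-of-ratios scaling (adjusted p = 0.040) and without vehicle 2 or siRNA 3. The ATF4 list met it under quantile normalization (adjusted p = 0.00088), with the filter of 5 FPKM and among protein-coding genes, and both met it with no filter, as did the cholesterol and ERK lists. The criterion for lists was therefore widened after their values were seen, to a call in at least 1 comparison with vehicle, medians of opposite sign and a called direct difference, which 7 lists met.

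The median log2 difference, WB436B minus STAT3 siRNA, was 0.63 for G2/M genes, 0.33 for glycolysis, -0.80 for ATF4 and stress response genes, 0.76 for cholesterol biosynthesis, 0.38 for fatty acid synthesis, 0.31 for ERK targets and 0.32 for TGF-beta response genes. With an estimated correlation the direct difference was not called for glycolysis (adjusted p = 0.15), TGF-beta response genes (adjusted p = 0.13) or fatty acid synthesis (adjusted p = 0.10). Length and GC content were argued against, as each list kept at least 0.886 of the difference between its median under WB436B and its median after the siRNA, both against vehicle, when their trend was removed, although the median of the direct difference went from 0.63 to 0.48 for G2/M genes. A single library was also argued against, as the smallest median in its own direction without 1 library was 0.0287, although the glycolysis call after the siRNA was lost without siRNA 3 (-0.15, adjusted p = 0.051) and the G2/M list was called under WB436B without vehicle 2 (0.22, adjusted p = 0.049) or siRNA 3 (0.21, adjusted p = 0.045). Under 4 other scalings all 7 lists had a called difference. The G2/M, ATF4, cholesterol, fatty acid and ERK lists kept opposite signs (smallest median in its own direction 0.0449). Against vehicle, quantile normalization nevertheless left the G2/M, cholesterol, fatty acid and ERK lists uncalled under WB436B (camera adjusted p = 0.76, 0.49, 0.56 and 0.78). It called only the ATF4 list of these 5 (adjusted p = 0.00088). On FPKM as deposited the fatty acid list had a median of 0.12 but a mean of -0.01 under WB436B, and fry called it lower (fry adjusted p = 0.0064). The WB436B medians of TGF-beta genes (-0.0224) and glycolysis (-0.0132) crossed 0 under quantile normalization, that of glycolysis also without mitochondrially encoded genes (-0.00288). Scaling stays open for the opposite signs of the TGF-beta and glycolysis lists. A different action of the compound and the siRNA, or of transfection, remains open and untested.

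Among single genes, H19 differed by -4.50 on the log2 scale, with 75.3, 624 and 26.0 FPKM under vehicle, siRNA and WB436B. PRSS1 differed by -3.18, and its decrease under WB436B was not called under quantile normalization. FOSL1 differed by 2.71, with 16.9, 11.3 and 80.1 FPKM in the 3 groups. PHLDA2 differed by 2.39, with 16.2, 5.996 and 35.7 FPKM. VIM differed by 2.29, with 4.07, 0.833 and 7.98 FPKM. PSAT1 differed by -2.55, with 36.7, 56.6 and 8.83 FPKM. BIRC5 differed by 1.24, with 6.13, 3.85 and 10.4 FPKM, and its siRNA call was lost without vehicle 1 (-0.56), vehicle 3 (-0.55), siRNA 1 (-0.46) or siRNA 2 (-0.50).

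The WB436B libraries held fewer genes at 1 FPKM or more, 10870 on average against 12236 under vehicle. Lower depth was argued against by a ratio of mean estimated depths, WB436B to siRNA, of 1.02, and a few genes taking more of the total by the share of the 50 most abundant genes, at most 40.5% in WB436B libraries and 40.9% to 45.2% in the others. A lower constant background, such as unspliced or genomic fragments, was estimated from 3348 genes at 0.5 to 1.5 FPKM, which fell by a median of 0.385 FPKM, and predicted -0.0572 for the median log2 fold change of 4514 genes at 5 to 20 FPKM. The observed value was -0.0014, above the prediction by 0.0558 (95% interval 0.0353 to 0.0771 from 2000 resamples), the side opposite to the one set down as evidence against it, and rescaling of FPKM after a loss of background could raise these genes by an amount not measured here. Background and an effect of the compound on weakly expressed genes both stay open.

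Some genes jumped between libraries of one group, with FPKM + 1 differing 4-fold or more, and 92 tested genes did so in at least 1 group (52 in vehicle, 45 in siRNA, 38 in WB436B). Too few fragments was argued against by the estimated fragments of 83 of them in the libraries of groups without a jump (median 187, 95% interval 113 to 429), and reassignment between transcripts of one gene by fewer annotated transcripts than in controls (medians 1.5 and 6, difference -4.5, interval -6 to -4). Of the jumping genes 72.8% shared exon bases with another gene model, against 46.3% of 920 control genes of like abundance (odds ratio 3.11, 95% interval 1.90 to 5.23). Reassignment of fragments between such gene models is therefore a candidate explanation for part of them, and TXNDC5, with 60.6% of its exon bases shared, is among them. No biological explanation was tested, as the jumps occur within groups.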

How the results depend on the processing

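The tests on protein-coding genes only, without genes that jumped within a group, with the length and GC trend removed and without mitochondrially encoded genes were chosen after the data were seen, and the other alternatives were planned. Of 99 list results 47 were called, 23 of them in all settings and 43 in all fits without 1 library. Of 455 results of named genes 440 were called, 409 and 436 of them likewise. Most of these genes were named for a large called change or a small p, so their shares do not carry over to other genes. STAT3 kept its direction and call in all model fits, from -2.42 to -2.07 after the siRNA and from -0.57 to -0.37 under WB436B. Exact permutation gave p = 0.1 for its changes of -2.12 and -0.516, the smallest that 3 against 3 libraries allow.

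The filter of 5 FPKM, which tests 7042 genes, left 2382 higher and 1756 lower after the siRNA, 2412 lower under WB436B, 2583 lower in the direct contrast and 2501 shared calls. A minimum of 1.5-fold left 861 higher and 1062 lower after the siRNA, 1167 and 2678 under WB436B, and 876 and 2532 in the direct contrast. There, median-of-ratios scaling called 4019 higher and quantile normalization 3585 lower, which moved the median of all genes by 0.183 and 0.180. Quantile normalization gave a correlation of fold changes of 0.569, against 0.531 (jackknife SE 0.02501) and 0.510 or more elsewhere. The cause of that change was not tested. Quantile normalization turned MT-ND4L (0.225) and MT-CYB (0.274) upward under WB436B and the ribosomal protein list to a called decrease in the direct contrast (-0.210). Median-of-ratios scaling, with or without the block, turned MCL1 upward there (0.0939, from -0.14), by construction, as it multiplies all genes of a library by one factor. Among lists that fry called, it pointed opposite to camera for fatty acid synthesis under WB436B (median 0.1195) and, in the direct contrast, for DNA replication (0.0371) and hypoxia genes (-0.121). For these 3 lists the tests differ in their reference. Camera compares with all other genes, and the median of all genes was -0.126 under WB436B and -0.185 in the direct contrast, while fry compares with 0. The cause of the reversals under quantile normalization was not tested. Of 52 list results not called, no filter brought 22 past the threshold, quantile normalization 12 in the same direction and the filter of 5 FPKM 7. Fry, the self-contained test, changed the most, with 42 called in the direction of camera and 3 in the opposite one. A list not called by camera is therefore not a list without change.

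Without 1 library, counts ranged from 3335 to 3780 higher and 2504 to 2817 lower after the siRNA, 2877 to 3176 and 4827 to 5220 under WB436B, and 2350 to 2613 and 5195 to 5677 in the direct contrast. Shared calls ranged from 3336 to 3689, the correlation from 0.522 to 0.551, and STAT3 from -2.15 to -2.07 and from -0.54 to -0.49. With 10 splits of 6 libraries a share under 0.05 cannot be reached. The real split alone, 1 of 10, gave as many calls in each comparison, 6638, 8402 and 8175, and the highest other split gave 3, 2 and 1. Every other split puts libraries of both groups on each side, so a real difference widens the spread it is tested against. Few calls in those splits are therefore no measure of unchanged groups.

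The replicate numbers were not treated as pairs. Correlations of deviations between same-numbered libraries were 0.0419 to 0.158 for siRNA and vehicle, where each exceeded all differently numbered pairs, -0.0442 to 0.0376 for WB436B and vehicle, and -0.0847 to -0.0196 for WB436B and siRNA. The replicate block called 3608 higher and 2704 lower after the siRNA, 3057 and 5095 under WB436B, and 2475 and 5484 in the direct contrast, or 3893 higher there together with median-of-ratios scaling. The block alone ended the calls of the squamous list under WB436B and of MT-CO2 in the direct contrast, and of no other called list or named gene. At 1 FPKM a gene of 1 kilobase rests on 14.9 to 47.2 fragments, which limits what can be called among weak genes.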

Other observations

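The grouping of genes into families by symbol and the test of tubulin genes were both chosen after the results were seen.

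Gene families, taken as symbols with a common stem and at least 10 tested members, were tested with camera over 132 families. Non-coding and antisense transcripts with such symbols were let in, and members were not checked for function. A family's description therefore belongs to its stem and need not hold for each member. None of the 10 families called after the siRNA or the 19 called under WB436B passed with an estimated correlation, whose adjusted p is given second. After STAT3 siRNA 9 of 11 annexin genes (ANXA, membrane-binding proteins) fell, with a median log2 fold change of -0.50 (adjusted p = 0.0015, and adjusted p = 0.44 with an estimated correlation). So did 6 of 10 SERPINB genes (intracellular serpins, median -0.74, adjusted p = 0.0015, then 0.44) and 8 of 12 tumour necrosis factor receptor genes (TNFRSF, median -0.56, adjusted p = 0.012, then 0.44). Genes with the stem MRPL, that of large-subunit proteins of the mitochondrial ribosome, rose in 31 of 49 after the siRNA (median 0.35, adjusted p = 0.0015, then 0.86). Under WB436B 33 of 49 rose (median 0.34, adjusted p = 1.1e-06, then 0.49). These medians kept their signs under the 3 other scalings.

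Under WB436B genes with the stem EIF, that of translation initiation factors, rose in 35 of 52 (median 0.35, adjusted p = 2.1e-06, and adjusted p = 0.24 with an estimated correlation). Of 10 UTP genes of the small-subunit processome 9 rose (median 0.89, adjusted p = 0.00013, then 0.24). Genes of the proteasome cap (PSMD) rose in 10 of 14 (median 0.47, adjusted p = 0.00020, then 0.24), nucleoporin genes (NUP) in 16 of 22 (median 0.43, adjusted p = 0.00060, then 0.49) and genes of the inner-membrane import machinery of mitochondria (TIMM) in 10 of 15 (median 0.58, adjusted p = 0.0022, then 0.24). Their signs were also kept under the 3 other scalings. Weakly expressed genes fell as a group under WB436B, and a test against all other genes is affected by that.

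The beta-tubulin gene TUBB fell from 261 ± 3.37 FPKM under vehicle to 97.9 ± 0.175 under WB436B, and TUBB4B from 264 ± 9.29 to 133 ± 4.19 FPKM. TUBA4A fell from 22.0 to 14.0, TUBB3 from 3.80 to 1.97, TUBA1C from 164 to 131 and TUBA1B from 315 to 235 FPKM, the last with adjusted p = 0.049. TUBA1B varied between vehicle libraries (standard deviation 72.1 FPKM). It shares 36.6% of its exon bases with a gene model that jumped within the siRNA and WB436B groups. Cells are known to degrade tubulin transcripts when free tubulin rises, and the hypothesis tested was that all alpha and beta tubulin transcripts are lower together under WB436B. Of 9 tested genes 6 fell and 0 rose. Their median log2 fold change was -0.39, the value of TUBA1B, against 0.03 in lists matched on abundance. Of 10000 matched lists 2.57% had a median as low. That lies between the bounds set for the hypothesis (1%) and against it (5%), so the test did not decide it. Other scalings gave 2.86%, 3.43%, 0.88% (quantile normalization) and 3.45%, and after STAT3 siRNA the share was 35.8%. In the direct contrast of WB436B with the siRNA, for which no bounds were set, the share was 7.02%, and 0.6% with quantile normalization. The fixed tubulin list was not called by camera under WB436B (adjusted p = 0.19), and a rise of free tubulin was not measured, so it may be only one of several explanations.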
